A study of Mus musculus with 6 samples.

How the data were processed

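Libraries were prepared by the submitters from total RNA of mouse lung or lung tumour with standard Illumina protocols after Trizol extraction and column purification, per the labels' protocols. The deposited table holds raw read counts per gene name, 1 column per library. Per the file headers, the authors counted reads with featureCounts 1.6.5 over exons grouped by gene name, with GENCODE vM1 annotation. Per the same header, a read that overlaps several names was counted for each of them, no strand setting was given, pairs were not joined into fragments, and multi-mapping reads were not requested. Antisense and overlapping genes can therefore share reads. The submitters' processing notes name STAR, limma, edgeR and R 3.6.0, and 2 genome builds, GRCm38 and mm9. The coordinates in the deposited table are those of mm9, the build of that annotation, and are given as such; the aligner's version is not given in the sources used here. The length column of the deposited table holds exon bases per name.

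The table has 33924 gene names, of which 7010 had no read in any library and 99 span several chromosomes. Mitochondrial ribosomal RNA took 17.6% to 25.3% of the counts and the 10 most abundant names 24.7% to 35.5%. Scgb1a1 took 0.906% to 1.42% of the counts in control lung. All columns were used, and each was assigned to its library by its name. Totals of 38996532 to 62336537 reads put 3 counts at 0.0481 to 0.0769 CPM in a single library.

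Genes were tested with edgeR 4.0.16 (R 4.3.3) on the counts as deposited: filterByExpr with its minimum count of 10, TMM scaling, the quasi-likelihood F test of tumour against control with group as the only term, and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 called changed. Standard errors were taken from the F statistic. CPM values are after TMM scaling, with a mean and SD over 3 libraries; log2 CPM used a prior count of 2. The 34 gene lists were fixed before the data were examined and hold markers of lung cell types and of pathways. Of 586 list entries, 558 matched by name, 17 through an older name, 10 were not matched, and 1 fell on the row of another. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation camera also uses only the 4 residual degrees of freedom of the fit, and far more with a preset one. Surfactant levels were compared with two-sided exact permutation tests. Where a group had no read, a fold is a bound against 3 counts over the group; with 1 to 3 reads, a ratio is given with an exact binomial 95% interval on the pooled reads.

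Named genes were set by a rule: the 8 largest and the 8 smallest log2 fold changes among changed genes with a mean log2 CPM of at least 2, no overlap between the groups, a proper gene symbol and no use in the check of sex-linked genes; the 2 members of each list with the smallest p; and 13 genes chosen in advance. Some genes that the rule takes are not reported here. Shared sequence is the share of 32-base words of a gene's longest transcript in GENCODE M21 that occur in another gene, and overlap is the share of exon bases inside exons of another name in the deposited table; M21 coordinates were not used.

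The gene test was tested on simulated data drawn from the control means, the library sizes and the fitted dispersions. With 19476 genes in the simulated test of tumour against control, it recovered 24% of 100 genes changed by 1 on the log2 scale. Of 100 changed by 2 it recovered 88%, and there were 11 false calls, 8.94% of all calls. No other gene was changed in the simulation, whereas 8397 of 20001 changed in the data. The adjustment was therefore stricter in the simulation, and these shares do not give the recovery in the real comparison. Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, a 2-fold test, a stricter threshold, each library left out, a replicate block, and, chosen after seeing the data, a correction for GC content and length by smooths (mgcv 1.9.3). Besides the deposited table, GENCODE M21 transcripts served for GC content and shared sequence, and a table of gene names for older symbols.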

Results

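Gene expression was measured by bulk RNA sequencing in lungs of FVB/NJ mice, an inbred strain. Mice received saline or the chemical carcinogen urethane (1 g per kg, by intraperitoneal injection), and tissue was taken at 6 months. The 6 libraries form 2 groups of 3: normal lung (control lung, replicates 1, 2 and 3) and urethane-induced lung tumour (replicates 1, 2 and 4). Counted reads per library were 38996532, 59037341 and 46025182 in control lung, and 58545354, 62336537 and 48509129 in the tumours. The labels do not say how tumour tissue was separated from the surrounding lung, or that each library came from its own animal. The p-values therefore measure the spread between these libraries, part of which may be technical. Between libraries of the same group, counts differed by more than sampling noise (chi-square per degree of freedom of 98 to 170 among controls and 69.7 to 305 among tumours), so none was treated as a second deposit of the same library. This does not show that they came from separate samples. Tumour replicate 2 had an Xist level of 3359 CPM (read counts scaled to library size) and at most 0.215 CPM of the Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y. The other 5 libraries had at most 32.9 CPM of Xist and at least 37.6 CPM of each Y-linked gene.

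The question stated for the series is which genes differ between control lung and urethane-induced tumours, and its title concerns markers of alveolar type 2 (AT2) cells, the surfactant-producing cells of the alveolus, in tumour cells. All 10 surfactant genes rose in the tumours, while all 19 ciliated cell markers and all 24 endothelial markers fell. Falls were also counted for 12 of 16 club cell markers, 20 of 21 T and NK cell markers and 12 of 15 B and plasma cell markers, and 1 club cell marker rose. None of these 6 lists passed with an estimated correlation between genes (camera adjusted p from 0.0705 to 0.362). In all, 8397 of the 20001 genes tested changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group), 3627 higher and 4770 lower in tumours. Of these, 2102 were at least 2-fold higher and 4015 at least 2-fold lower by the fitted fold change. CPM values of the groups did not overlap for 11200 genes, 56.0% of those tested, where chance gives 10% for 3 against 3. Without tumour replicate 2, the library that differs in sex-linked genes, 8163 genes changed. Without tumour replicate 1, 9436 did.

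All 10 surfactant and lamellar body genes rose, 10 of 10 also adjusted over the list alone, with a median log2 fold change of 1.85 (camera adjusted p = 4.16e-06, and adjusted p = 0.355 with an estimated correlation). Sftpc, which encodes surfactant protein C, averaged 5317 ± 1809.7 CPM in control lung and 18158 ± 7761 CPM in tumours (SD, n = 3 each), a log2 fold change of 1.77 ± 0.42 (SE) with an edgeR adjusted p = 0.00952. Without control replicate 3 the adjusted p for Sftpc was 0.0563. Against a 2-fold threshold Sftpc, Abca3 and Nkx2-1 did not pass (adjusted p = 0.0746, 0.0899 and 0.166). Sftpd had the largest rise of the list, 3.01 ± 0.35 (adjusted p = 0.000281), with 312 ± 72.4 CPM in control lung and 2514 ± 994 CPM in tumours. The log2 fold changes of Sftpa1, Sftpb and the cathepsin gene Ctsh were 2.38 ± 0.45, 1.91 ± 0.28 and 2.31 ± 0.24, with edgeR adjusted p of 0.00353, 0.000848 and 0.00016. Lamp3, a lamellar body membrane protein, rose by 1.86 ± 0.37 and the lipid transporter Abca3 by 1.29 ± 0.18 (adjusted p = 0.00443 and 0.000668). Nkx2-1, the lung lineage transcription factor, averaged 47.6 ± 9.01 CPM in control lung and 115 ± 29.3 CPM in tumours, a log2 fold change of 1.28 ± 0.22 (adjusted p = 0.00233).

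**Figure D1:**
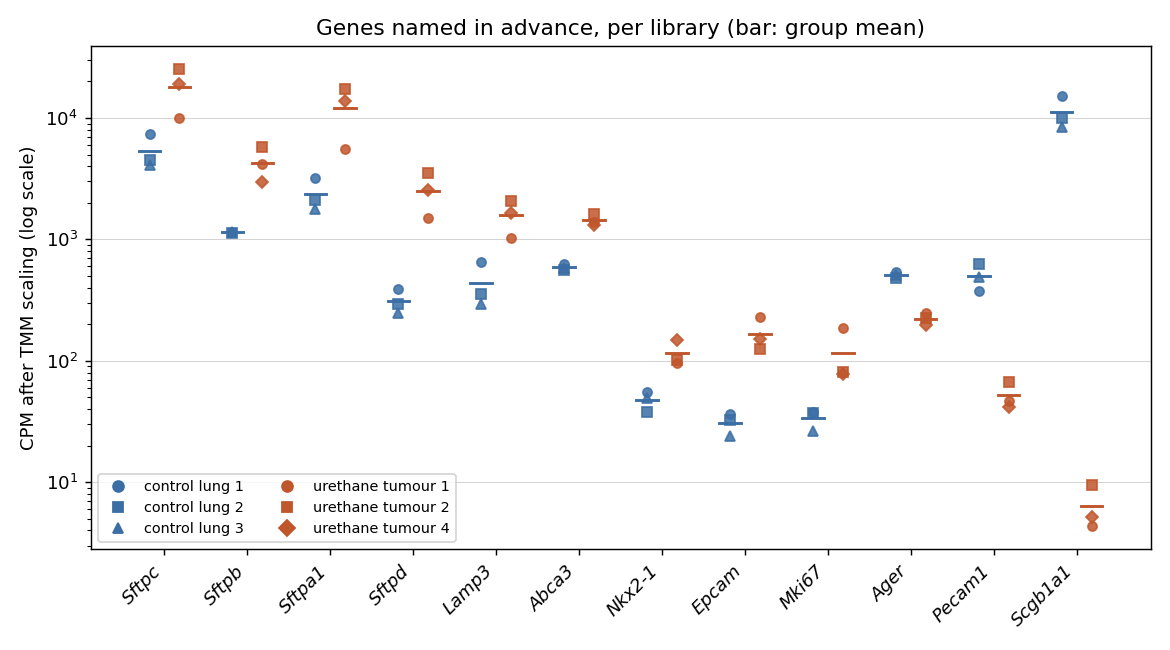
CPM after TMM scaling, on a log axis, of genes chosen before the data were examined; each point is a library and each bar the mean of the 3 libraries of a group. For Sftpd the tumour libraries lie at 1504, 3491 and 2546 CPM, above every control, and for Scgb1a1 at 4.32, 9.52 and 5.18 CPM, below every control.

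Among 24 other AT2 markers, 16 rose and 2 fell (16 rose and 3 fell adjusted over the list alone). Their median was 1.27 log2 units (camera adjusted p = 4.21e-05, and adjusted p = 0.378 with an estimated correlation). Cebpa, a transcription factor of AT2 cells, rose by 2.92 ± 0.26 on the log2 scale (adjusted p = 8.16e-05). The 2 members that fell were Lyz1, a lysozyme gene, at -6.64 ± 0.53 (adjusted p = 5.27e-05), and Mid1ip1 at -1.07 ± 0.29 (adjusted p = 0.0174). Of the 32-base words of the Lyz1 transcript, 33.0% also occur in another gene, and 25.5% of the exon bases of Mid1ip1 lie in exons of another gene name, so both values may include or lack reads of other genes. The adjusted p of Mid1ip1 was 0.0659 without control replicate 1. The mean log2 CPM of the surfactant list was 9.43 ± 0.31 in control lung and 11.32 ± 0.45 in tumours (SD, n = 3), a difference of 1.89. Set against the mean of the AT1, club, endothelial and fibroblast lists, it was 2.47 ± 0.43 and 7.46 ± 0.38, a difference of 4.99. For both measures a two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow.

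Most markers of the other lung epithelial cells were lower in tumours. Of 18 markers of alveolar type 1 (AT1) cells, the flat gas-exchange cells, 13 fell and 1 rose (2 rose and 14 fell adjusted over the list alone). Their median was -2.24 log2 units (camera adjusted p = 9.81e-08, and adjusted p = 0.355 with an estimated correlation). Ager fell from 511 ± 32.3 CPM in control lung to 223 ± 25.6 CPM in tumours (log2 fold change -1.20 ± 0.16, adjusted p = 0.000614), Scnn1g by 3.41 ± 0.22 and Pxdc1 by 3.50 ± 0.23 (listed under its older name 1300014I06Rik). The member that rose, the water channel gene Aqp5, had a log2 fold change of 0.82 ± 0.27 with an adjusted p of 0.0397, which was 0.0733, 0.138, 0.0929 and 0.108 without control replicates 1, 2 and 3 and tumour replicate 2, each left out alone. Club cell markers, genes of the secretory cells of the airway, counted 12 that fell and 1 that rose of 16 (1 rose and 13 fell adjusted over the list alone). Their median was -4.24 log2 units (camera adjusted p = 2.29e-15, and adjusted p = 0.0705 with an estimated correlation). Scgb1a1, the club cell secretory protein gene, fell from 11212 ± 3441 CPM in control lung to 6.34 ± 2.79 CPM in tumours, a log2 fold change of -10.79 ± 0.55 (adjusted p = 1.29e-05). Scgb3a2 and Gabrp fell by 10.01 ± 0.27 and 9.79 ± 0.33 (adjusted p = 1.60e-06 and 3.19e-06). The member that rose was Bpifa1, a secreted airway protein gene, at 6.48 ± 1.42 (adjusted p = 0.00708), with 95.2, 13.6 and 1.84 CPM in tumour replicates 1, 2 and 4; its log2 fold change was 4.27 without tumour replicate 1 and 7.10 without control replicate 3, and limma-voom gave it an adjusted p = 0.0998. All 19 ciliated cell markers fell, 19 also adjusted over the list alone, with a median of -5.17 (camera adjusted p = 4.29e-24, and adjusted p = 0.170 with an estimated correlation). Dnah5, an axonemal dynein gene listed as Dnahc5, fell by 9.56 ± 0.44 (adjusted p = 9.73e-06), and Ccdc153 had 1 read over the 3 tumour libraries, 2514-fold fewer after scaling to library size than in controls (95% counting interval 451 to 99339). Without tumour replicate 4, which held that read, Ccdc153 was at least 601-fold lower. Without tumour replicates 1 and 2 the ratio was 1570 (282 to 62048) and 1655 (297 to 65392).

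Most markers of endothelial, mesenchymal, muscle and mesothelial cells were also lower. All 24 endothelial markers fell (24 adjusted over the list alone). Their median was -3.26 log2 units (camera adjusted p = 4.29e-24, and adjusted p = 0.170 with an estimated correlation): Pecam1, an adhesion molecule of endothelial junctions, averaged 498 ± 126 CPM in control lung and 52.0 ± 13.4 CPM in tumours (log2 fold change -3.26 ± 0.27, adjusted p = 6.07e-05). Icam2 and the receptor gene Calcrl had -4.01 ± 0.21 and -4.83 ± 0.26 (adjusted p = 1.39e-05 for both). Fibroblast and matrix genes fell in 19 of 22 cases (19 adjusted over the list alone). Their median was -2.16 log2 units (camera adjusted p = 1.37e-12, and adjusted p = 0.170 with an estimated correlation), with the fibroblast transcription factor Tcf21 at -6.28 ± 0.22 and the matrix protein gene Npnt at -3.83 ± 0.16. Smooth muscle and pericyte markers showed 13 lower and 1 higher of 14 (1 rose and 13 fell adjusted over the list alone). Their median was -2.67 log2 units (camera adjusted p = 2.30e-07, and adjusted p = 0.246 with an estimated correlation), with Itga8 at -6.14 ± 0.35, Des, the desmin gene, at -3.70 ± 0.30, and Cox4i2, a respiratory chain subunit gene, the 1 member higher, at 1.24 ± 0.28 (adjusted p = 0.00780). All 12 cardiac muscle genes fell (12 adjusted over the list alone). Their median was -5.33 log2 units (camera adjusted p = 1.19e-05, and adjusted p = 0.355 with an estimated correlation). Of these, Actc1, cardiac actin, fell from 49.7 ± 36.3 CPM in control lung to 0.0229 ± 0.0199 CPM in tumours (adjusted p = 5.64e-05), and Myl7 had 2 reads over the tumour libraries, 2296-fold fewer after scaling to library size (95% counting interval 635 to 18966). Mesothelial markers fell in 7 of 8 cases (7 adjusted over the list alone). Their median was -4.40 log2 units (camera adjusted p = 0.00174, and adjusted p = 0.195 with an estimated correlation), with Gpm6a at -6.06 ± 0.63 and Upk3b at -4.97 ± 0.58. Of 6 nerve and Schwann cell markers, 3 fell (3 adjusted over the list alone). Their median was -2.36 log2 units (camera adjusted p = 0.0157, and adjusted p = 0.246 with an estimated correlation), with Pmp22 at -5.15 ± 0.39, Prx at -4.04 ± 0.39 and Cdh19 at -4.96 ± 0.76. Prx is also on the endothelial list. Cdh19 had 4 tumour reads, a ratio of 35.7 (95% counting interval 13.6 to 133), which was 23.5 (8.96 to 87.5) without tumour replicate 2 and 51.2 (13.9 to 427) without tumour replicate 4. Without control replicate 2 the ratio of Myl7 was 1013 (280 to 8375) and the log2 fold change of Upk3b -4.36. Without tumour replicate 1 the ratio of Myl7 was 1434 (397 to 11847). Without tumour replicate 2, which held its tumour reads, Myl7 was at least 1008-fold lower, and Gpm6a had a log2 fold change of -7.21. List medians were the same when genes with no reads in a group were set to their bound.

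**Figure D2:**
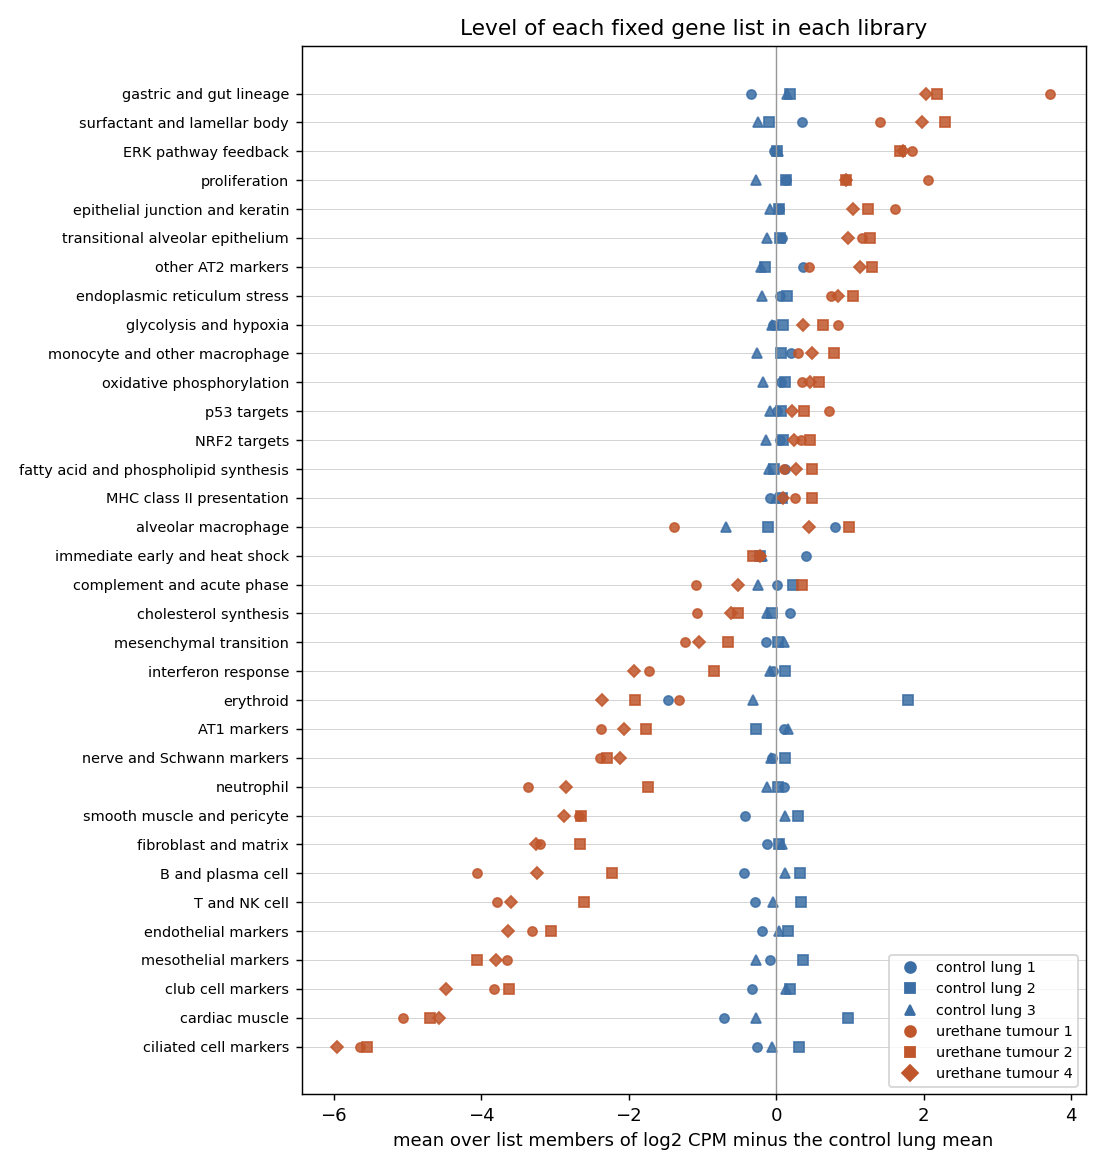
Mean over the tested members of each of the 34 gene lists of log2 CPM minus the control lung mean, in log2 units; each point is a library, with colours for groups and shapes for replicates. Tumour libraries lie between -5.95 and -5.54 for ciliated cell markers and between 1.41 and 2.30 for surfactant genes, and between -1.38 and 0.99 for alveolar macrophage genes.

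Most lymphocyte and neutrophil genes were lower in tumours, and macrophage lists did not pass. Of 21 T and NK cell markers, 20 fell (20 adjusted over the list alone). Their median was -3.29 log2 units (camera adjusted p = 1.28e-08, and adjusted p = 0.355 with an estimated correlation). Ncr1 and Klrd1, receptors of NK cells, had log2 fold changes of -5.24 ± 0.44 and -5.11 ± 0.48 (adjusted p = 6.39e-05 and 0.000105), and Klrd1 had -5.78 without tumour replicate 2. Foxp3, the regulatory T cell transcription factor, was the member that did not pass, at 7.08 ± 0.960 CPM in control lung and 6.73 ± 0.20 CPM in tumours (adjusted p = 0.80). B and plasma cell markers fell in 12 of 15 cases (13 adjusted over the list alone). Their median was -2.91 log2 units (camera adjusted p = 4.77e-06, and adjusted p = 0.362 with an estimated correlation), with Pax5 at -6.31 ± 0.51. Neutrophil genes fell in 11 of 13 cases and rose in 1 (1 rose and 11 fell adjusted over the list alone). Their median was -2.87 log2 units (camera adjusted p = 0.00544, and adjusted p = 0.394 with an estimated correlation): Camp, an antimicrobial peptide gene, had -4.58 ± 0.46, and Hdc, histidine decarboxylase, rose by 2.61 ± 0.21 (adjusted p = 5.66e-05). Alveolar macrophage genes rose in 2 and fell in 1 of 15 cases (1 rose and 1 fell adjusted over the list alone). Their median was 0.57 log2 units (camera adjusted p = 0.438), with the lipid binding protein genes Fabp4 and Fabp5 at 1.77 ± 0.35 and 0.98 ± 0.33, and Cidec, a lipid droplet gene, at -4.42 ± 0.49. Other monocyte and macrophage genes rose in 7 and fell in 3 of 18 cases (7 rose and 3 fell adjusted over the list alone). Their median was 0.53 log2 units (camera adjusted p = 0.108), with the lipopolysaccharide co-receptor Cd14 at 2.01 ± 0.19 and the chemokine receptor Ccr2, Csf1r and Nr4a1 at -2.08 ± 0.21, -0.95 ± 0.23 and -1.49 ± 0.27. Without tumour replicate 1, these macrophage lists passed, with adjusted p of 0.0346 and 0.0137; the second also passed without tumour replicate 4 (adjusted p = 0.0418). Fabp5 had an adjusted p of 0.150, 0.161, 0.119 and 0.0758 without control replicates 2 and 3 and tumour replicates 2 and 4, and Csf1r 0.0507 without control replicate 3. Erythroid genes fell in 3 of 5 cases (4 adjusted over the list alone). Their median was -3.20 log2 units (camera adjusted p = 0.401). Control replicate 2 weighed on these: without it Hbb-b1, Hbb-b2 and Hba-a1, globin genes that share sequence with close copies, had log2 fold changes of -1.27, -1.43 and -1.47 (adjusted p = 0.0979, 0.0918 and 0.231), compared with -3.61, -3.20 and -3.95 with all 6 libraries. Without tumour replicate 4 their adjusted p were 0.0786, 0.0691 and 0.0948. Without tumour replicate 2, Hbb-b1 and Hba-a1 had 0.0524 and 0.0748, and without control replicate 3 Hba-a1 had 0.0595.

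Epithelial junction and keratin genes rose in 12 of 16 cases (13 adjusted over the list alone). Their median was 1.59 log2 units (camera adjusted p = 1.87e-06, and adjusted p = 0.246 with an estimated correlation). Epcam, an epithelial adhesion molecule, rose from 30.8 ± 6.33 CPM in control lung to 168 ± 53.6 CPM in tumours (log2 fold change 2.45 ± 0.27, adjusted p = 0.000208), the splicing factor Esrp1 by 2.31 ± 0.14 and the transcription factor Grhl2 by 1.78 ± 0.15. Genes of transitional alveolar epithelium, a state seen during repair, rose in 7 and fell in 1 of 15 cases (8 rose and 1 fell adjusted over the list alone). Their median was 1.28 log2 units (camera adjusted p = 0.00537, and adjusted p = 0.195 with an estimated correlation). Clu, clusterin, rose by 4.75 ± 0.34 and Areg, an EGF receptor ligand, by 4.10 ± 0.43 (adjusted p = 3.31e-05 and 0.000165). The member that fell, Plaur, had -0.64 ± 0.21 (adjusted p = 0.0432), which was 0.128, 0.133, 0.0716, 0.0663 and 0.10 without control replicates 1, 2 and 3 and tumour replicates 1 and 4, each left out alone. Krt8, Krt18 and Krt19 are on both lists. Of 17 gastric and gut lineage genes, 12 passed the low count filter, of which 7 rose and 1 fell (7 rose and 1 fell adjusted over the list alone). The median of these 12 was 2.70 log2 units (camera adjusted p = 4.02e-05, and adjusted p = 0.328 with an estimated correlation). A member near 0 in control lung could be tested only where tumours were high. Cldn2, a tight junction protein of leaky epithelia, rose from 0.468 ± 0.10 CPM in control lung to 176 ± 7.19 CPM in tumours (log2 fold change 8.52 ± 0.22, adjusted p = 1.60e-06), and the endodermal transcription factor Foxa3 by 5.96 ± 0.43. Tff2, a trefoil factor, was the member that fell, with 204 reads in control lung and 2 in tumours, 109-fold fewer after scaling to library size (95% counting interval 29.9 to 909.8, adjusted p = 0.00162). Without tumour replicate 1, which held both reads, Tff2 was at least 45.6-fold lower. Without tumour replicate 2 the ratio was 72.0 (19.7 to 599).

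Proliferation genes rose in 18 of 25 cases (19 adjusted over the list alone). Their median was 1.66 log2 units (camera adjusted p = 6.17e-05, and adjusted p = 0.453 with an estimated correlation, directional fry adjusted p = 0.0542). Mki67 averaged 33.7 ± 6.55 CPM in control lung and 115 ± 62.4 CPM in tumours (log2 fold change 1.77 ± 0.36, adjusted p = 0.00460), with 187, 80.9 and 77.6 CPM in tumour replicates 1, 2 and 4. Cenpf, a kinetochore gene, and Ccnb1, cyclin B1, rose by 2.34 ± 0.35 and 2.44 ± 0.38; 46.8% of the 32-base words of Ccnb1 occur in another gene. Feedback genes of the ERK pathway rose in 15 and fell in 1 of 18 cases (15 rose and 1 fell adjusted over the list alone). Their median was 1.29 log2 units (camera adjusted p = 1.28e-08, and adjusted p = 0.0705 with an estimated correlation). Etv4, an ETS transcription factor, rose from 0.487 ± 0.0926 CPM in control lung to 23.9 ± 11.5 CPM in tumours (log2 fold change 5.60 ± 0.41, adjusted p = 3.48e-05), and Dusp5, an ERK phosphatase, by 2.0 ± 0.16. The member that fell was Fosl1 (-1.28 ± 0.39, adjusted p = 0.0309), whose exons overlap another name over 68.1% of their bases; its adjusted p was 0.132 and 0.0698 without control replicates 2 and 3, and 0.0849 and 0.0747 without tumour replicates 2 and 4.

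Glycolysis and hypoxia genes rose in 12 and fell in 3 of 22 cases (15 rose and 3 fell adjusted over the list alone). Their median was 0.65 log2 units (camera adjusted p = 0.00249, and adjusted p = 0.362 with an estimated correlation), with Ldha, lactate dehydrogenase A, at 2.06 ± 0.17 and Hk2, hexokinase 2, at 1.92 ± 0.19. The 3 that fell were Adm, Slc16a3 and Pfkp (-2.41 ± 0.41, -0.95 ± 0.21 and -1.09 ± 0.20); 33.2% of the words of Ldha are shared. Oxidative phosphorylation genes rose in 9 of 23 cases (9 adjusted over the list alone). Their median was 0.47 log2 units (camera adjusted p = 0.00851, and adjusted p = 0.444 with an estimated correlation), with Cyc1 at 1.14 ± 0.22 and Sdhd at 0.67 ± 0.14. Endoplasmic reticulum stress genes rose in 10 and fell in 1 of 16 cases (11 rose and 1 fell adjusted over the list alone). Their median was 1.0 log2 units (camera adjusted p = 0.000395, and adjusted p = 0.362 with an estimated correlation): the disulfide isomerases Pdia6 and Pdia4 rose by 1.85 ± 0.18 and 1.68 ± 0.18, and Ddit3 had -0.57 ± 0.19 (adjusted p = 0.0422, and 0.163, 0.0810, 0.0855, 0.0721, 0.0728 and 0.0913 without control replicates 1, 2 and 3 and tumour replicates 1, 2 and 4, each left out alone). Cholesterol synthesis genes fell in 11 of 19 cases (12 adjusted over the list alone). Their median was -0.83 log2 units (camera adjusted p = 0.0267, and adjusted p = 0.491 with an estimated correlation), with Sqle at -1.13 ± 0.19. This list did not pass without control replicate 1 (adjusted p = 0.0687) or tumour replicate 1 (adjusted p = 0.0973). Interferon response genes fell in 15 of 20 cases (15 adjusted over the list alone). Their median was -1.26 log2 units (camera adjusted p = 0.000611, and adjusted p = 0.378 with an estimated correlation), with Ifit2 at -3.07 ± 0.17 and Ifit3 at -4.10 ± 0.29; 61.1% of the words of Ifit3 are shared with another gene. Mesenchymal transition genes rose in 3 and fell in 10 of 14 cases (3 rose and 10 fell adjusted over the list alone). Their median was -1.98 log2 units (camera adjusted p = 0.0350, and adjusted p = 0.417 with an estimated correlation). Mmp2, a matrix metalloproteinase, had -3.98 ± 0.32, while Sox9, a transcription factor of the embryonic lung tip, rose from 0.204 ± 0.105 CPM in control lung to 58.5 ± 22.1 CPM in tumours (log2 fold change 8.14 ± 0.44, adjusted p = 1.39e-05). Hmga2 and Mmp14 also rose, by 1.34 ± 0.33 and 0.63 ± 0.21, and the adjusted p of Mmp14 was 0.121, 0.101 and 0.0886 without control replicates 1 and 2 and tumour replicate 2. Without tumour replicate 1 the camera adjusted p of this list was 0.0852. Fibroblast and matrix genes, endothelial markers and T and NK cell markers fell too (medians -2.16, -3.26 and -3.29), and epithelial junction and keratin genes rose (median 1.59). These bulk values therefore do not place the rises or falls of the pathway lists in tumour cells.

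The remaining 6 lists did not pass camera. Fatty acid and phospholipid synthesis genes rose in 9 and fell in 4 of 20 cases (9 rose and 4 fell adjusted over the list alone). Their median was 0.17 log2 units (camera adjusted p = 0.0648), with the malic enzyme gene Me1 at 3.13 ± 0.25, and Gpam, Thrsp, Chpt1 and Lpin1 at -3.23 ± 0.25, -1.48 ± 0.37, -0.66 ± 0.17 and -0.88 ± 0.19. The adjusted p of Thrsp was 0.0502 without control replicate 2, and that of Chpt1 0.0525 and 0.0568 without control replicate 1 and tumour replicate 4. NRF2 targets rose in 7 and fell in 1 of 17 cases (9 rose and 1 fell adjusted over the list alone). Their median was 0.54 log2 units (camera adjusted p = 0.0648). The member that fell, Nqo1, a quinone reductase, had -2.71 ± 0.35 (adjusted p = 0.00046), and Me1 is also on this list. Targets of p53 rose in 7 and fell in 1 of 16 cases (7 rose and 1 fell adjusted over the list alone). Their median was 0.63 log2 units (camera adjusted p = 0.0502), with Cdkn1a, the p21 gene, at 1.68 ± 0.19, Zmat3 at 1.24 ± 0.16 and Sesn1 at -1.30 ± 0.19. Genes of MHC class II presentation rose in 7 and fell in 3 of 11 cases (7 rose and 3 fell adjusted over the list alone). Their median was 1.24 log2 units (camera adjusted p = 0.0543), with H2-DMb1 at 1.52 ± 0.14 and, among those that fell, H2-Ob, H2-Oa and Cd86 at -2.95 ± 0.27, -2.31 ± 0.34 and -1.09 ± 0.30. The adjusted p of Cd86 was 0.0781 and 0.0686 without control replicates 1 and 2. These 4 lists passed without tumour replicate 4, with adjusted p of 0.0463, 0.0392, 0.0180 and 0.0168; the first 2 also passed without tumour replicate 1 (adjusted p = 0.0138 and 0.0348), and the p53 list without control replicate 2 (adjusted p = 0.0460). Immediate early and heat shock genes rose in 1 and fell in 6 of 16 cases (1 rose and 6 fell adjusted over the list alone). Their median was 0.05 log2 units (camera, which pointed down, adjusted p = 0.551), with Ier3 at -2.46 ± 0.19, Dusp1 at -2.32 ± 0.30 and Hsph1, a heat shock protein gene, at 1.18 ± 0.18. Complement and acute phase genes rose in 4 and fell in 6 of 13 cases (4 rose and 7 fell adjusted over the list alone). Their median was -1.01 log2 units (camera adjusted p = 0.755); Lcn2, lipocalin 2, rose by 4.53 ± 0.45 (adjusted p = 0.000137, log2 fold change 3.93 without tumour replicate 2), Orm1, Cfb and Lrg1 by 2.18 ± 0.30, 1.19 ± 0.19 and 1.96 ± 0.30, and C1s had -2.31 ± 0.27. Shares of words found in another gene were 33.7% for Me1, 35.7% for H2-DMb1 and 35.6% for C1s, so these values are uncertain.

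The genes with the largest rises were near or at 0 in control lung. Gkn2, a gastric mucosal protein gene (chromosome 6, 87323359 to 87329488), had no read in the 3 controls and 152, 39.5 and 7.98 CPM in tumour replicates 1, 2 and 4 (adjusted p = 0.00240). Its pooled level was at least 3686-fold higher, against a floor of 3 counts over the group. Npy2r, a neuropeptide Y receptor (chromosome 3, 82342305 to 82352008), and Serpinb5, maspin (chromosome 1, 108757750 to 108779925), also lacked reads in controls and were at least 1259-fold and 789-fold higher (adjusted p = 8.73e-05 and 0.000187). The cytochrome P450 gene Cyp2c40 (chromosome 19, 39841561 to 39887304) was at least 441-fold higher, but 83.8% of its 32-base words occur in another gene, so its identity is uncertain. Dlk1, a non-canonical Notch ligand of fetal tissues (chromosome 12, 110691033 to 110701546), averaged 0.223 ± 0.386 CPM in control lung and 689.9 ± 406 CPM in tumours (log2 fold change 11.35 ± 1.18, adjusted p = 0.000165). Raet1d, a ligand of the NK cell receptor NKG2D (chromosome 10, 22081700 to 22093945), rose by 9.98 ± 0.26, with 57.1% of its words shared. Tmem27 (chromosome X, 160526762 to 160556792) and the adhesion receptor gene Gpr128 (chromosome 16, 56724722 to 56795968) rose by 9.83 ± 0.49 and 9.75 ± 0.84 (adjusted p = 1.21e-05 and 7.07e-05). Single libraries moved some of these. The lowest bound with a library left out was 1278-fold for Gkn2 (without tumour replicate 1), 714-fold for Npy2r and 447-fold for Serpinb5 (both without control replicate 2), and 239-fold for Cyp2c40 (without tumour replicate 2). Without tumour replicate 1 the log2 fold changes of Gpr128 and Dlk1 were 8.70 and 10.75. Control replicate 2 held all control reads of Dlk1, and without it Dlk1 was at least 20729-fold higher. Without the same library Tmem27 had 2 control reads, a ratio of 1872 (95% counting interval 518 to 15463). All positions are mm9.

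**Figure D3:**
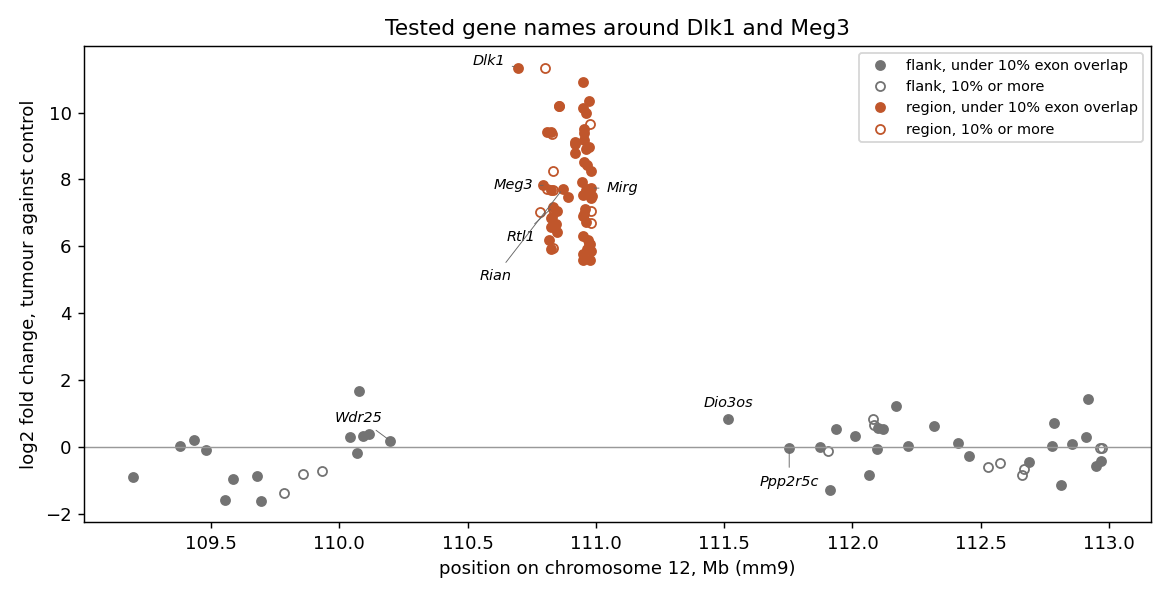
Log2 fold change of tumour against control for each tested gene name within 2 Mb of the interval from Dlk1 to Mirg, by its midpoint on chromosome 12 in Mb (mm9); filled points have under 10% of their exon bases inside another name. The 65 tested names of the interval are all higher in tumours, many of them tested only because tumours were high. The 50 names of the flanks lie between -1.61 and 1.67.

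The genes with the largest falls included genes of motile cilia and heart muscle. Cyp2a5, a cytochrome P450 gene (chromosome 7, 27620324 to 27628567), had 33.0 ± 10.4 CPM in control lung and no tumour read, at least 1877-fold lower (adjusted p = 3.26e-05); 57.5% of its words are shared. The cilia genes Spag16 (chromosome 1, 69873562 to 70771706), Dynlrb2 (chromosome 8, 119028915 to 119039796) and Ttc29 (chromosome 8, 80737196 to 80918225), together with Kndc1 (chromosome 7, 147080595 to 147127436), had no tumour read. They were at least 651-fold, 487-fold, 456-fold and 564-fold lower (adjusted p = 3.89e-05, 3.87e-05, 5.31e-05 and 4.45e-05). Csrp3, a muscle LIM protein gene (chromosome 7, 56085768 to 56103400), was at least 524-fold lower (adjusted p = 0.000654). Ccdc108 (chromosome 1, 74948645 to 74982173) had 2 tumour reads, 3402-fold fewer after scaling to library size (95% counting interval 942 to 28101). Actc1 (chromosome 2, 113873018 to 113879284), described with the cardiac list, completes these 8. Without control replicate 2 the log2 fold change of Actc1 was -10.10, and Csrp3 was at least 239-fold lower. The lowest bounds of Cyp2a5, Spag16, Dynlrb2, Ttc29 and Kndc1 with a library left out were 1173-fold, 407-fold, 304-fold, 285-fold and 352-fold, each without tumour replicate 1. Without tumour replicate 4, which held its reads, Ccdc108 was at least 1627-fold lower. Without tumour replicates 1 and 2 its ratio was 2125 (588 to 17552) and 2240 (620 to 18498). The bounds and intervals cover counting error only.

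Camera passed 25 of the 34 lists, 10 up and 15 down, with its preset correlation of 0.01. With the correlation between genes estimated from the 6 libraries, none passed (lowest adjusted p = 0.0705, 7 lists at an unadjusted p under 0.05). This setting also lowers the degrees of freedom of the camera test to the 4 residual ones, so the drop is not an effect of correlation alone. The transitional alveolar epithelium list lost its call with an estimate of -0.00896 (unadjusted camera p from 0.00316 to 0.0344). Directional fry, which tests each list by itself and not against other genes, passed 27. Members outside the naming rule, given where they went against their list, were chosen after their values were seen.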

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

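All alternatives were fixed before the data were examined, except the correction for GC content and length. The count of changed genes was 8397 and stayed within 1.5 times under DESeq2 (9311), limma-voom (8550), RLE, upper quartile and no scaling, other filters, library sizes without the 50 most abundant genes, an adjusted p under 0.01 (5628), the GC and length correction (8823) and each library left out (6421 to 9436). It was 3965 when tested against a 2-fold change, a stricter hypothesis by construction. Library totals alone moved the median log2 fold change of all tested genes by -0.115 and gave 2551 higher and 5033 lower. Libraries numbered 1 and 2 exist in both groups, but nothing says that a number marks a shared animal or day, and deviations of same-numbered libraries from their group means correlated at -0.182 and -0.00858 across genes. With the replicate number as a block over these 4 libraries, 3571 genes changed and 25 lists passed, against 4794 genes in the same 4 libraries without the block, so fewer libraries account for part of the drop. Of the 25 lists passing with the block, 24 also passed in the main fit. Mesenchymal transition lost its call (camera adjusted p = 0.0682) and p53 targets gained one (camera adjusted p = 0.0386). The 25 lists passing camera became 0 with an estimated correlation. For the ERK list the estimate was -0.0253, under the preset 0.01, yet its unadjusted camera p went from 2.26e-09 to 0.00294. A higher correlation therefore does not account for the change in that list. With an estimated correlation, camera also uses only the 4 residual degrees of freedom of the fit, and far more with a preset one. Fewer degrees of freedom raise p for the same statistic, and their share in the change of the other lists was not tested. The other alternatives gave 25 to 29 lists, and leaving out libraries 24 to 30. The differences of 4.99 and 1.89 for the AT2 measures kept their direction in every alternative run, always at the smallest exact permutation p of 0.1, from 4.82 to 5.24 and from 1.70 to 2.17 without single libraries. Of 138 genes taken by the naming rule or added to it, 136 kept their direction in all 18 alternatives and 94 also their side of the threshold; 34 lost their call under the replicate block, among them Sftpc, Sftpa1, Lamp3, Abca3 and Nkx2-1 (adjusted p from 0.0545 to 0.235), and 33 against a 2-fold change, among them Ager, Aqp5, Cox4i2, Cyc1, Fosl1, Hbb-b1, Plaur, Sqle and Zmat3. The 2 exceptions were Col14a1, which ranged from -1.32 to 1.87 without single libraries, and Foxp3, from -0.17 to 0.0226; the cause was not tested. Of the lists, alveolar macrophage turned down under the replicate block (adjusted p = 0.961) and complement and acute phase turned up without tumour replicate 1, with adjusted p from 0.203 to 0.940 over the left-out libraries; the cause was not tested. At this depth a gene with no read in a group lies under 0.0197 CPM in control lung or 0.0184 CPM in tumours.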

Other observations

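The test of a higher share of AT2 cells and both tests on tumour replicate 1 were chosen after the result was seen, as was the correction for GC content and length as an alternative; the other tests were fixed before their results were seen. Names from Dlk1 to Mirg, part of the Dlk1-Dio3 imprinted region on chromosome 12 (mm9, 110691033 to 110987665), rose together in the tumours: all 65 tested names of this interval passed the test and were higher. Many of them had few or no control reads and passed the low count filter only because tumours were high. For those names a rise was largely fixed by the filter. Meg3, Rian, Mirg and Rtl1 had 1009, 1054, 72 and 131 control reads. Dio3os, at the Dio3 end of the region and outside this interval, had a log2 fold change of 0.82 ± 0.42 and did not pass (adjusted p = 0.150). Genes named here for this region, other than Dlk1, were chosen after their values were seen. Meg3, a long noncoding RNA, went from 6.61 ± 1.95 CPM in control lung to 1499.6 ± 206 CPM in tumours (SD, n = 3), a log2 fold change of 7.82 ± 0.32 (SE) with an edgeR adjusted p = 4.97e-06. Rian, Mirg and Rtl1 had log2 fold changes of 7.71 ± 0.27, 7.74 ± 0.28 and 7.18 ± 0.26 (adjusted p = 3.19e-06, 3.25e-06 and 3.25e-06). In normal tissue Dlk1 and Rtl1 are expressed from the paternal allele, and Meg3, Rian and Mirg from the maternal one. Antisense and overlapping genes can share reads here, and Mir433 and Mir127, within the Rtl1 span, lie wholly in exons of another name. The rise of Rtl1 therefore cannot be assigned to the paternal allele. In tumour replicates 1, 2 and 4, Dlk1 had 1155, 511 and 403 CPM, and Meg3 1347, 1418 and 1734 CPM.

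A gain of the surrounding part of chromosome 12 would raise its neighbours too: the 50 tested names within 2 Mb on either side had a median log2 fold change of -0.0284, with 5 higher and 5 lower, which argues against it. Double counting under names with shared exons does not account for all of the rise. With under 10% of their exon bases inside another name, 53 names of the region had a log2 fold change above 5. Exon overlap cannot test for reads of an unspliced transcript, however. Small names such as Mir341 and Mir154 lie within the spans of Rian and Mirg without sharing exons, so their rises may not be separate. Loss of imprinting at many loci might raise imprinted genes elsewhere. Of 22 tested, 3 rose (13.6%) and 9 fell, where 3627 and 4770 of all 20001 tested genes did. Those that rose were Phlda2, Peg10 and Igf2r (2.59 ± 0.53, 2.18 ± 0.51 and 0.64 ± 0.18), and those that fell included Igf2 (-2.69 ± 0.41) and Cdkn1c (-3.56 ± 0.31). These counts cannot decide the question, because markers of many cell types fell in this bulk tissue, which could hide a modest rise. The adjusted p of Peg10 was 0.0540 without control replicate 3 and that of Igf2r 0.0723, 0.0649 and 0.0635 without control replicates 1, 2 and 3, while Phlda2 had 1.98 without tumour replicate 1, and 76.0% of the words of Igf2 are shared. A regional change of expression on both parental alleles, or outgrowth of a cell that already used the region, may account for the rise; counts per gene do not separate alleles, so neither was tested.

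All 24 endothelial, all 19 ciliated and 12 of 16 club cell markers fell, while all 10 surfactant genes and 16 of 24 other AT2 markers rose; 1 club cell marker rose, 2 of the other AT2 markers fell, and the macrophage lists had medians of 0.57 and 0.53, with alveolar macrophage levels of -1.38, 0.99 and 0.44 over the control mean in tumour replicates 1, 2 and 4. A pattern made by GC content or transcript length would shrink under a correction for both: the medians of the surfactant, endothelial and ciliated lists kept at least 0.99 of their size, which argues against it as the cause. A higher share of AT2 cells with no change inside them cannot raise any gene more than the most AT2-specific ones, yet 76 genes with a mean log2 CPM of 2 or more rose above Sftpd by more than 2 standard errors and 38 above Chi3l1, the AT2 marker with the largest rise on these lists (3.88 ± 0.44; 3.29, with 63 genes above it, without tumour replicate 2), among them Sox9 (8.14 ± 0.44) and Cldn2 (8.52 ± 0.22). The 76 genes are not all separate cases: Dlk1, Meg3, Rian, Mirg and Rtl1 lie in the same region. Others, such as Gkn2 and Npy2r, had no control read, so the size of their fitted rise is uncertain. The rule of 2 standard errors was not adjusted for the number of genes. A higher share of tumour cells that resemble AT2 cells, together with changed expression in them, could account for these values and stays a hypothesis. Heart muscle genes in control lung (Actc1, 49.7 ± 36.3 CPM in control lung) and airway genes are also what a block of lung with its large vessels and airways would hold, so how tissue was taken may add to the falls, and this was not tested.

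Tumour replicate 1 lies apart from tumour replicates 2 and 4: its counts differed from theirs with a chi-square per degree of freedom of 305 and 241, against 69.7 between those 2. Its mean level over the control mean was 2.06 for proliferation genes, against 0.95 and 0.95 in replicates 2 and 4, and -1.38 for alveolar macrophage genes, against 0.99 and 0.44. Sex of the animal does not separate it, since its Xist level was 5.82 CPM and the library with high Xist is tumour replicate 2; sequencing depth does not either, since its total of 58.55 (in units of 1e6 reads) lies between 48.51 and 62.34. The median level of each chromosome's genes relative to control lung, minus that of all other genes, ran from -0.27 (X) to 0.43 (17) in tumour replicate 1, from -0.06 to 0.07 in replicate 2 and from -0.14 to 0.12 in replicate 4, and the spread of the fitted GC and length trend was 0.528, 0.236 and 0.354. Bias from GC content or length, altered chromosome numbers, and the grade or cell content of the tumour may account for the difference, and all of these stay open, as none was tested.

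Col14a1, a collagen gene chosen after its values were seen, had 1.33 (adjusted p = 0.325) with all libraries and -1.32 (adjusted p = 0.00159) without tumour replicate 1. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05: 1 split, the real one, gave as many changed genes. It gave 8397, or 9960 at an unadjusted edgeR p under 0.05. The highest of the others gave 0 with edgeR and 0 with limma-voom, or 829 at the same unadjusted threshold. Every other split mixes tumour and control libraries in both groups, so the difference between tissues adds to the spread within each group. Their low counts follow from this and do not measure false calls.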
